A study of Mus musculus with 10 samples.

How the data were processed

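Flash-frozen mouse liver was extracted with an RNeasy kit, and libraries were made from 200 ng of total RNA with poly-A selection and a TruSeq kit. The submitters' notes name the aligner STAR and the build mm10, without versions. The read counter, the annotation and the scaling method are not given in the sources used here. The deposited table holds a normalised signal for 24062 genes in 10 libraries. Every value of a library was a whole number of reads, within 0.01 reads, times 1 constant for that library, so whole reads were recovered from the values. The recovered totals ran from 23206229 to 30137802 reads per library, and the implied scaling factors from 0.847 to 1.153 with a product of 1.0. A value of 0 allows up to 3 reads, and such floors and the intervals of read shares cover counting error only. No column was left unmapped and no symbol was duplicated.

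Groups, comparisons, tests, 35 gene lists and the rule for named genes were fixed before the data were examined. The edgeR and DESeq2 fits were chosen after seeing the data, as were all tests of explanations. Values were taken as log2(value + 1), and genes with a value of at least 1 in at least 2 of the 10 libraries were tested, which left 12648 genes. 6447 genes were 0 in all libraries. Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) with 1 mean per combination of diet and treatment and a term for duration, so that the pools of 12 and 24 weeks served as repeats with 3 residual degrees of freedom. The tumour comparison took all 10 libraries and had 4. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05.

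Named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes whose change had the same sign in both pairs and whose mean lay at or above the median of tested genes. Up to 4 called members of each list, or 2 uncalled members given as values, were added, and 16 genes were always followed, of which 1 is not reported here. Of 798 list entries, 788 matched the table's symbols, 7 matched by an older symbol and 3 (Ly6g, Es31 and Ahsp) did not match. The 31 lists with at least 5 tested members were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. No list kept its call with an estimated correlation in any comparison. Lowest adjusted p-values there were 0.337 for CCl4 on normal diet, 0.509 for the diet, 0.321 for the joint exposure, 0.264 for CCl4 on Western diet, 0.543 for the interaction, 0.408 for duration and 0.411 for tumours. Coordinates come from the GENCODE annotation of GRCm38.

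The alternatives were a pseudocount of 0.1, no filter, a stricter filter, quantile normalization, median-ratio size factors, no trend, no duration term, all 10 libraries in 1 fit, array weights, leaving out each library, fry, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A library left out leaves a lone pool in its combination, which is then assumed to vary like the others. The fits were tested on simulated data. For CCl4 on normal diet, 58% of simulated changes of 1 on the log2 scale were recovered and 89.8% of changes of 2, with 12 false calls among 12352 genes. For the interaction 25% and 92% were recovered, with 13 false calls among 12342 genes. There 0% of changes of 0.585 and 83.7% of changes of 3 were recovered. For duration 83% and 100% were recovered, with 8 false calls among 12348, and for tumours 64.6% and 91.7%, with 8 among 12349. Only 47 to 50 genes were changed at each size. False calls are therefore a far larger share of the calls than of the tested genes, and that share was not computed. The simulated tumours were given the spread of the liver pools. The real tumours differed more from each other than the pools did, so recovery and false calls there may be worse than simulated. Raw sequence reads were not used here. The 6 called interaction genes outside the rule for named genes are given in the closing section because each called gene of that comparison is listed.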

Results

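Messenger RNA was sequenced from livers of mice fed a normal or a Western diet and given carbon tetrachloride (CCl4), a hepatotoxin that the enzyme Cyp2e1 activates, or its oil vehicle. The 8 liver libraries were each a pool of 4 mice, with 1 pool for every combination of 2 diets, 2 treatments and 2 durations (12 and 24 weeks). Another 2 libraries came from liver tumours of single mice given Western diet and CCl4 for 24 weeks. No condition had a replicate pool. Read totals at 12 and 24 weeks were 24975517 and 24082712 for normal diet with oil, and 24368431 and 30137802 for normal diet with CCl4. They were 25265767 and 27165428 for Western diet with oil and 25532382 and 29491139 for Western diet with CCl4. Tumours 1 and 2 had 23206229 and 29693666 reads. Values are normalised read counts, and changes are log2 fold changes with the standard error of the fit, 2 pools against 2 unless stated. All genes called in a comparison moved in the same direction in both of its pairs. In the liver comparisons, adjusted p-values weigh each change against the spread between pools of 12 and 24 weeks, not between animals. A shift with duration that all combinations share is taken out of that spread. In the tumour comparison the spread also takes in the difference between the 2 tumours, from single mice.

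CCl4 on a normal diet was compared with oil on a normal diet, to ask what the toxin did alone. Collagen and macrophage genes rose together. The type I collagen gene Col1a1 rose by 3.74 ± 0.27 (adjusted p = 0.000103) and Col3a1 by 3.01 ± 0.19. In the list of extracellular matrix genes, 31 of 35 measured members rose and 1 fell, or 32 and 1 adjusted over the list alone (camera adjusted p = 6.01e-14, adjusted p = 0.371 with an estimated correlation). Among markers of recruited macrophages, 18 of 20 measured members rose and 1 fell, with equal counts adjusted over the list alone (camera adjusted p = 3.39e-10, adjusted p = 0.337 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 4.99 ± 0.37, Mmp12, a macrophage elastase, by 4.29 ± 0.31, and the lipid receptor Trem2 by 2.55 ± 0.32. Cholesterol synthesis fell almost as a whole: 1 of 26 measured members rose and 23 fell, with equal counts adjusted over the list alone (camera adjusted p = 2.38e-17, adjusted p = 0.337 with an estimated correlation). Squalene epoxidase (Sqle) changed by -4.12 ± 0.15 (adjusted p = 6.47e-06) and isopentenyl diphosphate isomerase (Idi1) by -3.73 ± 0.21. Lipid droplet and lipid uptake genes rose, and 17 of 20 measured members rose and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 1.16e-09, adjusted p = 0.337 with an estimated correlation). The droplet protein gene Cidec rose by 5.45 ± 0.56, the apolipoprotein gene Apoa4 by 5.32 ± 0.22 and the fatty acid transporter Cd36 by 2.47 ± 0.11.

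Cell cycle, interferon-stimulated, class II and chemokine genes also rose with CCl4 on a normal diet. Of the cell cycle list, 28 of 34 measured members rose and 0 fell, or 29 and 0 adjusted over the list alone (camera adjusted p = 3.39e-10, adjusted p = 0.371 with an estimated correlation), with the proliferation marker Mki67 up by 1.81 ± 0.31. Interferon-stimulated genes followed, and 20 of 26 measured members rose and 0 fell, or 21 and 0 adjusted over the list alone (camera adjusted p = 8.95e-09, adjusted p = 0.371 with an estimated correlation), with Oasl2 up by 2.28 ± 0.29. For class II antigen presentation, 9 of 10 measured members rose and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 1.73e-06, adjusted p = 0.337 with an estimated correlation). For chemokines and inflammatory cytokines, 16 of 27 measured members rose and 1 fell, or 22 and 1 adjusted over the list alone (camera adjusted p = 8.02e-08, adjusted p = 0.337 with an estimated correlation). Of T and NK cell markers, 2 of 14 measured members rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.313, adjusted p = 0.490 with an estimated correlation). Of B and plasma cell markers, 0 of 8 measured members rose and 0 fell, with equal counts adjusted over the list alone, and 3 had an unadjusted p under 0.05 in limma (camera adjusted p = 0.175, adjusted p = 0.637 with an estimated correlation). In the hepatocyte identity list, 0 of 24 measured members rose and 8 fell, or 0 and 15 adjusted over the list alone (camera adjusted p = 7.87e-07, adjusted p = 0.371 with an estimated correlation). Of periportal hepatocyte genes, 0 of 18 measured members rose and 8 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.00160, adjusted p = 0.371 with an estimated correlation). Of pericentral ones, 2 of 22 measured members rose and 6 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.378, adjusted p = 0.807 with an estimated correlation). In the list of drug-metabolising cytochromes P450, 4 of 26 measured members rose and 14 fell, or 4 and 15 adjusted over the list alone (camera adjusted p = 0.000194, adjusted p = 0.371 with an estimated correlation). Cyp1a2, which metabolises caffeine, changed by -2.04 ± 0.25, while Cyp2b9 rose by 3.40 ± 0.37. Genes that male livers express more than female livers fell, and 0 of 24 measured members rose and 21 fell, or 0 and 23 adjusted over the list alone (camera adjusted p = 1.64e-12, adjusted p = 0.371 with an estimated correlation). Among them the fatty acid elongase Elovl3 changed by -3.66 ± 0.24. Of the circadian clock genes, 12 of 22 measured members rose and 5 fell, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.0260, adjusted p = 0.392 with an estimated correlation), and the clock output factor Dbp rose by 4.25 ± 0.21. Cyp2e1 itself read 6614 and 5765 in the oil pools of 12 and 24 weeks and 6858 and 4867 in the CCl4 pools, and did not pass the test (adjusted p = 0.793). In all, 3285 of 12648 tested genes changed, 1938 higher and 1347 lower, and 1172 of them by at least 2-fold. The count was 1021 without the normal-diet oil pool of 24 weeks, 1106 without the normal-diet CCl4 pool of 24 weeks and 1736 without the normal-diet CCl4 pool of 12 weeks. Of named genes past the threshold, 85 of the 119 stayed past it whichever pool was left out. The count of all genes was 1353 without the filter on low values and 437 with all 10 libraries in the fit.

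**Figure D1:**
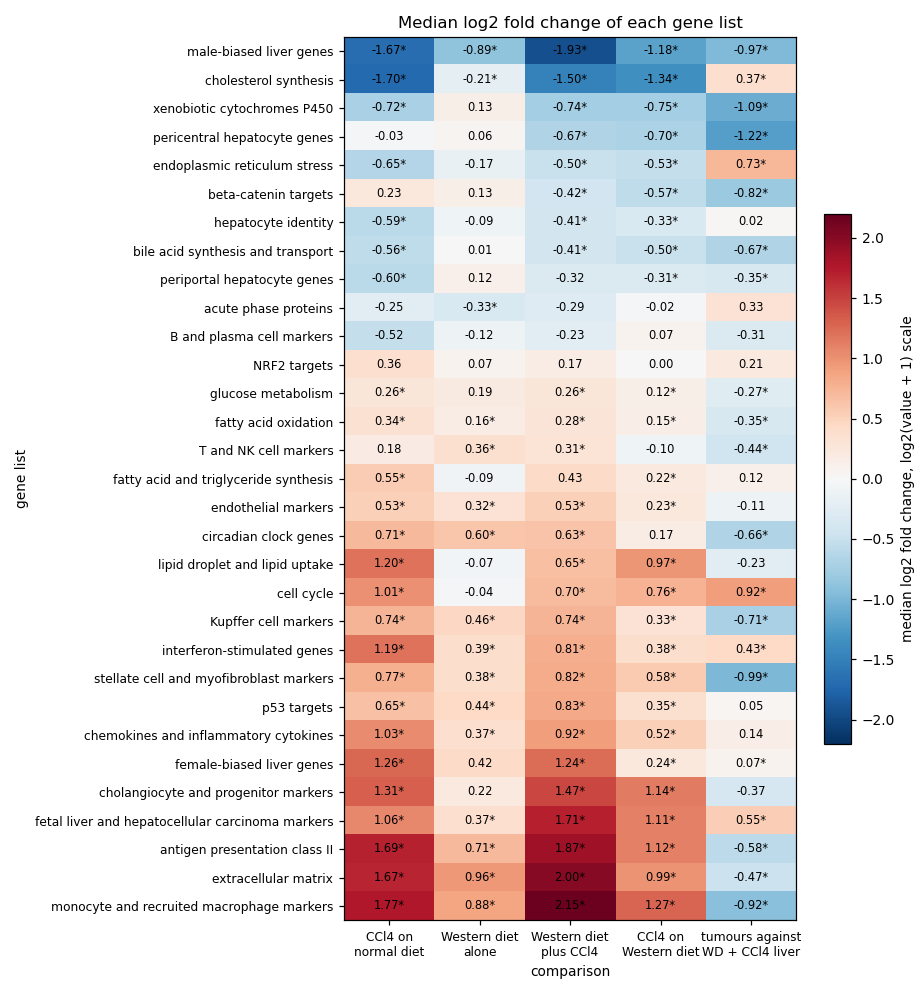
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), fitted over the 12-week and 24-week pools. An asterisk marks camera adjusted p under 0.05 with the preset correlation, and no list kept that call with an estimated correlation; cholesterol synthesis read -1.70 and -1.34 with CCl4 on the normal and the Western diet.

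Western diet with oil was compared with normal diet with oil, to ask what the diet did alone. Some matrix genes, macrophage markers and clock genes rose. Col1a1 rose by 2.32 ± 0.27 and Col3a1 by 1.91 ± 0.19, and Gpnmb by 4.11 ± 0.37. Of the extracellular matrix list, 12 of 35 measured members rose and 0 fell, or 26 and 1 adjusted over the list alone (camera adjusted p = 2.00e-14, adjusted p = 0.509 with an estimated correlation). Of the recruited macrophage markers, 9 of 20 measured members rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 3.99e-09, adjusted p = 0.509 with an estimated correlation), and the 1 that fell was the fatty acid binding protein Fabp5. Among circadian clock genes, 10 of 22 measured members rose and 0 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.509 with an estimated correlation). Dbp rose by 4.10 ± 0.21 (adjusted p = 0.000195), the period gene Per3 by 3.05 ± 0.34 and the protease Usp2 by 2.58 ± 0.33. The normalised count of Dbp was 1.46 and 2.10 in the oil pools on normal diet and 55.9 and 38.4 on Western diet. In the male-biased list, 0 of 24 measured members rose and 8 fell, or 0 and 14 adjusted over the list alone (camera adjusted p = 3.88e-11, adjusted p = 0.509 with an estimated correlation), with Elovl3 at -2.97 ± 0.24. The glutamate transporter Slc1a2 changed by -1.92 ± 0.24 and glutamine synthetase (Glul), a neighbour of the central vein, by -0.97 ± 0.20. Both belong to lists with few members past the threshold. Of pericentral genes, 1 of 22 measured members rose and 2 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.405, adjusted p = 0.873 with an estimated correlation). Of beta-catenin targets, 0 of 16 measured members rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.869, adjusted p = 0.956 with an estimated correlation). Cholesterol synthesis had no gene past the threshold over all genes: 0 of 26 measured members rose and 0 fell, or 1 and 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05 in limma (camera adjusted p = 0.00530, adjusted p = 0.708 with an estimated correlation). Sqle read 142 and 151 on normal diet and 106 and 139 on Western diet. Altogether 252 genes changed, 183 higher and 69 lower, 165 of them by at least 2-fold. The count was 17 without the Western-diet oil pool of 12 weeks, 22 without the Western-diet oil pool of 24 weeks, 34 without the normal-diet oil pool of 24 weeks, 105 without the normal-diet oil pool of 12 weeks and 390 without the Western-diet CCl4 pool of 24 weeks. Of named genes past the threshold, 4 of the 61, Cyp2a22, Cyp2c67, Dbp and Elovl3, stayed past it whichever pool was left out. The count of all genes was 0 without the filter (limma, with 2442 at an unadjusted p under 0.05), 4 with all 10 libraries in the fit, 121 without the duration term, 125 without the trend, 134 with quantile normalization and 570 with DESeq2. The 17 without the Western-diet oil pool of 12 weeks were 6 higher and 11 lower.

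**Figure D2:**
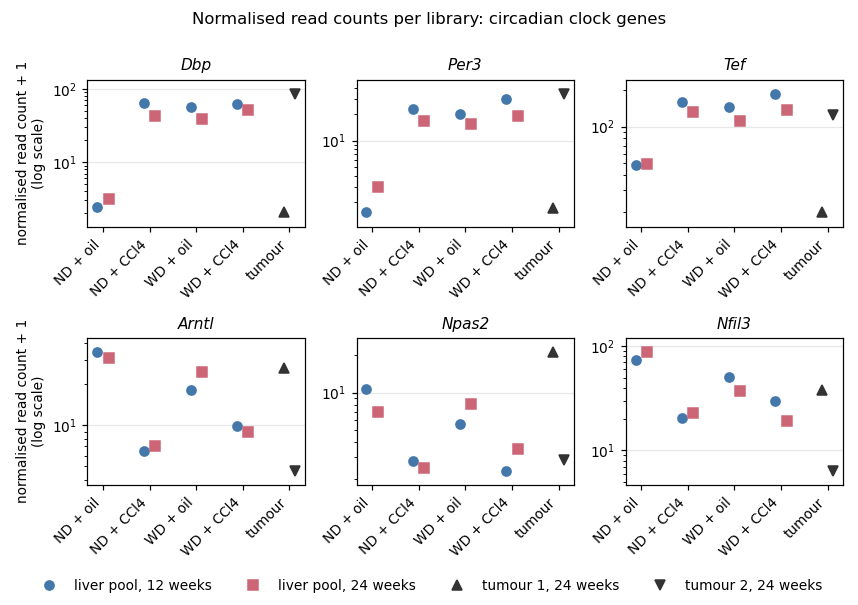
Normalised read count plus 1 (log axis) of 6 clock genes in each library, with 1 point per liver pool of 4 mice (ND, normal diet, WD, Western diet) and 1 per tumour. Dbp read 1.46 and 2.10 in the normal-diet oil pools and 1.06 and 85.3 in tumours 1 and 2.

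Western diet plus CCl4 was compared with normal diet plus oil, the joint exposure that the series is about. Scar, macrophage and fetal liver genes rose, and some hepatocyte genes of the central vein fell. Col1a1 rose by 4.36 ± 0.27 and Gpnmb by 6.07 ± 0.37. Of the extracellular matrix list, 31 of 35 measured members rose and 1 fell, or 33 and 1 adjusted over the list alone (camera adjusted p = 7.81e-16, adjusted p = 0.339 with an estimated correlation). Of the recruited macrophage markers, 18 of 20 measured members rose and 1 fell, with equal counts adjusted over the list alone (camera adjusted p = 6.69e-12, adjusted p = 0.321 with an estimated correlation). For resident macrophages, the Kupffer cells, 8 of 15 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.000282, adjusted p = 0.385 with an estimated correlation). Marco and Timd4, receptors of Kupffer cells looked up after the values were seen, did not pass (adjusted p = 0.468 and 0.206) and were higher at 12 weeks and lower at 24. Marco read 10.8 and 34.6 in the normal-diet oil pools of 12 and 24 weeks and 37.4 and 1.61 in the joint pools, and Timd4 read 5.32 and 7.96 in the former and 7.30 and 0.862 in the latter. Markers of stellate cells, which make the scar, rose too, and 13 of 19 measured members rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 7.25e-05, adjusted p = 0.343 with an estimated correlation), with the growth factor receptor Pdgfrb up by 2.08 ± 0.23. Of bile duct and progenitor markers, 10 of 19 measured members rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.14e-05, adjusted p = 0.385 with an estimated correlation), including osteopontin (Spp1) at 2.52 ± 0.47. In the list of fetal liver and hepatocellular carcinoma markers, 16 of 22 measured members rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 1.64e-08, adjusted p = 0.321 with an estimated correlation). The surface protein gene Ly6d rose by 5.03 ± 0.20, the glypican gene Gpc3 by 1.83 ± 0.26 and alpha-fetoprotein (Afp) by 1.38 ± 0.38. The imprinted RNA H19 rose by 5.37 ± 0.91, though it read 139 and 18.0 in the joint pools of 12 and 24 weeks.

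In the pericentral list, 1 of 22 measured members rose and 10 fell, or 1 and 13 adjusted over the list alone (camera adjusted p = 5.40e-06, adjusted p = 0.385 with an estimated correlation). Ornithine aminotransferase (Oat) changed by -3.35 ± 0.47, Slc1a2 by -2.85 ± 0.24 and Glul by -1.49 ± 0.20. Cholesterol synthesis fell here as well, and 0 of 26 measured members rose and 23 fell, or 0 and 24 adjusted over the list alone (camera adjusted p = 5.07e-16, adjusted p = 0.321 with an estimated correlation), with Idi1 at -3.27 ± 0.21. For bile acid synthesis and transport, 4 of 25 measured members rose and 9 fell, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.00226, adjusted p = 0.321 with an estimated correlation). There the organic anion transporter Slco1a1 changed by -4.81 ± 0.61 and Cyp7b1, a hydroxylase of the alternative bile acid pathway, by -3.92 ± 0.31. The male-biased list fell nearly whole, and 0 of 24 measured members rose and 23 fell, with equal counts adjusted over the list alone (camera adjusted p = 5.34e-14, adjusted p = 0.339 with an estimated correlation), with Elovl3 at -5.75 ± 0.24. Clock genes moved here too, 12 of 22 measured members rose and 5 fell, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.00964, adjusted p = 0.385 with an estimated correlation). The largest falls included the urinary protein genes Mup7, Mup14 and Mup21 and the antitrypsin gene Serpina1e, whose families share near-identical sequence, so which member changed is uncertain. In all, 3278 genes changed, 1984 higher and 1294 lower, 1293 of them by at least 2-fold. The count was 1214 without the normal-diet oil pool of 24 weeks and 1669 without the Western-diet CCl4 pool of 24 weeks. Of named genes past the threshold, 94 of the 126 stayed past it whichever pool was left out. The count of all genes was 1887 without the filter and 796 with all 10 libraries in the fit.

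**Figure D3:**
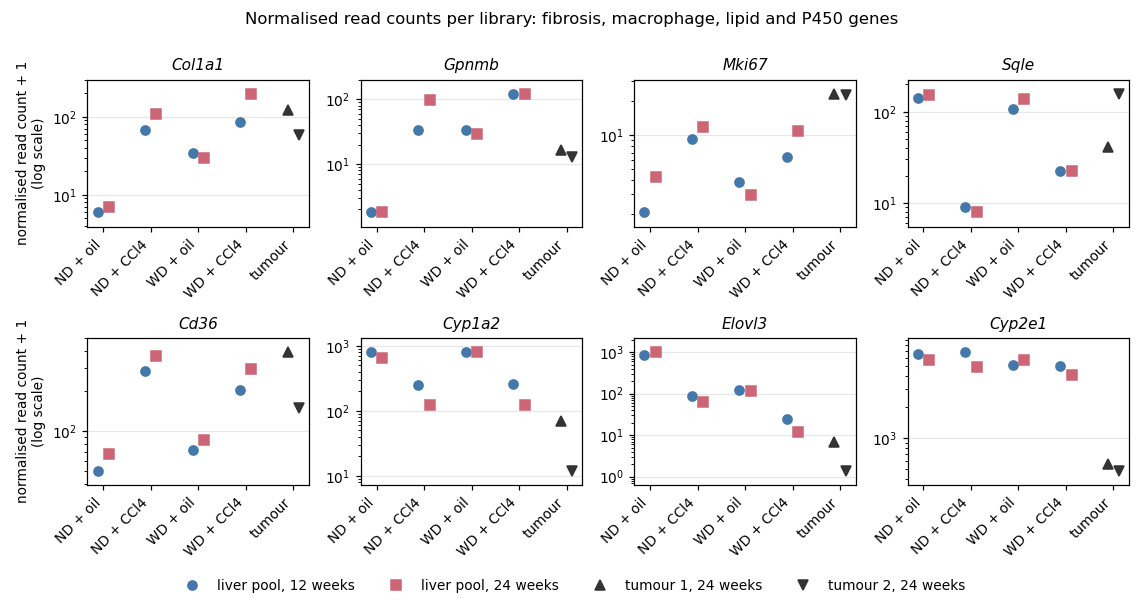
Normalised read count plus 1 (log axis) of 8 genes in each library, with 1 point per liver pool of 4 mice (ND, normal diet, WD, Western diet) and 1 per tumour. Gpnmb read 0.799 and 0.823 in the normal-diet oil pools, 121 and 120.3 in the Western-diet CCl4 pools and 15.3 and 12.0 in the tumours.

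Western diet plus CCl4 was also compared with Western diet plus oil, to ask what CCl4 added to the diet. Cholesterol synthesis fell, and 0 of 26 measured members rose and 23 fell, or 0 and 24 adjusted over the list alone (camera adjusted p = 5.58e-25, adjusted p = 0.264 with an estimated correlation). Idi1 changed by -2.92 ± 0.21, Cyp51, the lanosterol demethylase, by -2.51 ± 0.13, and Sqle by -2.45 ± 0.15. Of the recruited macrophage markers, 15 of 20 measured members rose and 0 fell, or 18 and 0 adjusted over the list alone (camera adjusted p = 4.75e-13, adjusted p = 0.314 with an estimated correlation). Of lipid droplet and lipid uptake genes, 10 of 20 measured members rose and 0 fell, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.02e-09, adjusted p = 0.301 with an estimated correlation), with Apoa4 up by 2.87 ± 0.22 and Cd36 by 1.63 ± 0.11. Lcn2, an iron-sequestering lipocalin of injured epithelium and neutrophils, rose by 3.20 ± 0.26, Ly6d by 3.92 ± 0.20 and the steroid hydroxylase Cyp17a1 by 2.33 ± 0.20. In the P450 list, 1 of 26 measured members rose and 13 fell, or 2 and 17 adjusted over the list alone (camera adjusted p = 4.96e-08, adjusted p = 0.330 with an estimated correlation), with Cyp2c29 at -3.12 ± 0.20. The Cyp2c genes are close paralogs, so which member changed is uncertain. In the pericentral list, 0 of 22 measured members rose and 8 fell, or 1 and 15 adjusted over the list alone (camera adjusted p = 1.28e-09, adjusted p = 0.368 with an estimated correlation). In the periportal list, 1 of 18 measured members rose and 5 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.474 with an estimated correlation). Altogether 862 genes changed, 543 higher and 319 lower, 384 of them by at least 2-fold. The count was 29 without the Western-diet oil pool of 24 weeks, 117 without the Western-diet oil pool of 12 weeks and 312 without the Western-diet CCl4 pool of 24 weeks. Of named genes past the threshold, 17 of the 100 stayed past it whichever pool was left out, among them Idi1, Sqle, Cd36 and Lcn2. The count of all genes was 3 without the filter, 6 with all 10 libraries in the fit, 203 without the duration term, 470 with quantile normalization and 1319 with DESeq2.

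The interaction of diet and CCl4 asks whether the joint change differed from the sum of the separate changes on the log2 scale, the closest test of the joint effect in the series title. Dbp, Apoa4 and Gstm3 changed less with both exposures than the sum of their separate changes. The interaction was -3.99 ± 0.30 for Dbp (adjusted p = 0.00471), -2.45 ± 0.31 for Apoa4, -2.00 ± 0.19 for the glutathione transferase Gstm3 and -1.46 ± 0.18 for the heparan sulfatase Sulf2. For Sqle it was 1.67 ± 0.21, where the change with CCl4 was -4.12 ± 0.15 on the normal diet and -2.45 ± 0.15 on the Western diet. Cidea, a lipid droplet gene, read 0 and 0.0915 with neither exposure, 16.4 and 34.4 with CCl4 alone and 0.154 and 0.919 with both. Col1a1 and Gpnmb did not pass (adjusted p = 0.225 and 0.1004), which does not show that their changes added up. Gpnmb read 0.799 and 0.823 with neither exposure, 32.3 and 98.4 with CCl4 alone, 33.2 and 27.8 with the diet alone and 121 and 120.3 with both. Col1a1 read 4.92 and 5.90, 67.2 and 106, 33.2 and 28.8, and 86.0 and 196 in the same order. In all, 13 genes passed, 7 with a positive and 6 with a negative interaction. That split moved with the setting: 4 were positive and 11 negative with a pseudocount of 0.1, 3 and 6 with edgeR, 37 and 95 with DESeq2, and 25 and 54 without the Western-diet CCl4 pool of 24 weeks. The count was 0 without the Western-diet oil pool of 12 weeks or the Western-diet oil pool of 24 weeks (limma, with 615 to 682 at an unadjusted p under 0.05), 20 without the Western-diet CCl4 pool of 12 weeks, 21 without the normal-diet CCl4 pool of 24 weeks and 79 without the Western-diet CCl4 pool of 24 weeks. Of named genes past the threshold, 0 of the 7 stayed past it whichever pool was left out. The count of all genes was 0 without the filter or with all 10 libraries in the fit (limma, with 1346 and 320 at an unadjusted p under 0.05) and 7 without the trend.

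The pools of 24 weeks were compared with those of 12 weeks over all 4 combinations, to ask what duration did. No gene passed the limma test, whose smallest adjusted p was 0.187. At an unadjusted p under 0.05 there were 1475 genes against 632 expected by chance, edgeR called 1 gene and DESeq2 90. Itgax, an integrin of activated macrophages, read 6.26 and 20.2 in the joint pools of 12 and 24 weeks and 7.36 and 16.4 in the normal-diet CCl4 pools. Slco1a1 read 39.3 and 7.53 in those joint pools, and 180.2 and 11.6 in the normal-diet CCl4 pools. For class II antigen presentation, 0 of 10 measured members rose and 0 fell, or 7 and 0 adjusted over the list alone, and 8 had an unadjusted p under 0.05 in limma (camera adjusted p = 6.31e-08, adjusted p = 0.408 with an estimated correlation). For the male-biased genes, 0 of 24 measured members rose and 0 fell, or 0 and 10 adjusted over the list alone, and 13 had an unadjusted p under 0.05 in limma (camera adjusted p = 6.31e-08, adjusted p = 0.477 with an estimated correlation). The count reached 1 when either Western-diet CCl4 pool was left out. A contrast of the CCl4 pools of 24 weeks with those of 12 weeks, the highest of 32 splits of the pools and picked after their counts were seen, called 358 genes in limma.

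The 2 tumours, from single mice, were compared with the Western-diet CCl4 livers, to ask what marked tumour tissue. Some genes of the central vein fell, and some fetal liver and carcinoma markers rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -5.27 ± 0.59 (adjusted p = 0.0184) and uridine phosphorylase (Upp2) by -4.63 ± 0.33. Cyp2e1 changed by -3.02 ± 0.35 and read 5042 and 4068 in the liver pools and 556 and 478 in the tumours. In the pericentral list, 0 of 22 measured members rose and 5 fell, or 0 and 12 adjusted over the list alone (camera adjusted p = 4.20e-11, adjusted p = 0.411 with an estimated correlation). Of the beta-catenin targets, 0 of 16 measured members rose and 2 fell, with equal counts adjusted over the list alone (camera adjusted p = 3.83e-05, adjusted p = 0.411 with an estimated correlation). The desaturase Scd2 rose by 2.78 ± 0.36, Lcn2 by 2.97 ± 0.39, the Golgi protein gene Golm1 by 1.69 ± 0.24 and the oxidative stress gene Osgin1 by 2.67 ± 0.32. Of the fetal liver and carcinoma markers, 4 of 22 measured members rose and 0 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00545, adjusted p = 0.424 with an estimated correlation). For the cell cycle list, 0 of 34 measured members rose and 0 fell, or 14 and 0 adjusted over the list alone, and 17 had an unadjusted p under 0.05 in limma (camera adjusted p = 2.15e-11, adjusted p = 0.424 with an estimated correlation). Mki67 read 5.38 and 9.91 in the pools and 22.2 and 21.7 in the tumours. Gpnmb changed by -3.23 ± 0.43. Of stellate cell markers, 0 of 19 measured members rose and 2 fell, or 0 and 12 adjusted over the list alone (camera adjusted p = 3.18e-08, adjusted p = 0.411 with an estimated correlation). The myofibroblast marker Acta2, which did not pass, read 3.34 and 5.89 in the pools and 44.9 and 7.65 in the tumours. The tumours differed from each other: Gpc3 read 1.76 and 371 in tumours 1 and 2, Afp 3.83 and 54.1, H19 216 and 15.1 and Glul 529.9 and 62.7. In all, 123 genes changed, 59 higher and 64 lower, 118 of them by at least 2-fold. The count was 0 without 1 (any) of the 4 Western-diet pools (limma, with 1221 to 1585 at an unadjusted p under 0.05), 1 without the normal-diet oil pool of 24 weeks or the normal-diet oil pool of 12 weeks, 7 without the normal-diet CCl4 pool of 24 weeks, 8 without the normal-diet CCl4 pool of 12 weeks, 2259 without tumour 2 and 2394 without tumour 1. Of named genes past the threshold, 0 of the 34 stayed past it whichever library was left out. The count of all genes was 3 with array weights that let tumours and livers differ in spread, 214 with quantile normalization, 388 without the duration term and 745 with DESeq2.

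On the mouse assembly GRCm38 (mm10) some of the protein-coding genes named above lie as follows: Col1a1 at 94936224 to 94953042 of chromosome 11, Gpnmb at 49036546 to 49070929 of chromosome 6, Sqle at 59315077 to 59331192 of chromosome 15, Idi1 at 8885501 to 8892451 of chromosome 13, Dbp at 45705088 to 45710203 of chromosome 7, Elovl3 at 46131897 to 46135694 of chromosome 19, Cyp2e1 at 140763739 to 140774987 of chromosome 7 and Gpc3 at 52272426 to 52613950 of chromosome X.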

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

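All tests of explanations in this part were chosen only after the results had been seen, while the interaction itself was planned. Each gene here passed the interaction test, which asks whether the response to CCl4 differed between diets. Each list was called by camera with the preset correlation but by neither an estimated correlation nor fry. Outside those in the report, Cyp2a22, a P450 whose reads may be shared with paralogs, had an interaction of -2.75 ± 0.28 (adjusted p = 0.00832). The following 6 genes were named after their values were seen: Scara5, a ferritin receptor, at 2.54 ± 0.22, the trefoil gene Tff3 at 4.07 ± 0.34, the transcription factor Pitx3 at 2.34 ± 0.28, Enho, which encodes adropin, at 2.15 ± 0.28, the GTPase-activating gene Srgap3 at 2.57 ± 0.35, and the monooxygenase gene Moxd1 at 4.46 ± 0.41. Moxd1 read 14.4 and 30.4 in the normal-diet oil pools and was at 0 in the other 6 liver pools, at least 112-fold lower against a floor of 3 reads per library, so its fitted value depends on the pseudocount. With all Western-diet liver pools at 0, its response to CCl4 on that diet could not be measured. Tff3 read 22.3 and 36.3 in the normal-diet oil pools and 1.54 and 1.98 in the joint pools, and Scara5 read 2.31 and 4.93 with the Western diet alone and 14.1 and 22.4 with both exposures. Dbp stood at -3.99 ± 0.30, Apoa4 at -2.45 ± 0.31, Gstm3 at -2.00 ± 0.19, Sulf2 at -1.46 ± 0.18, Sqle at 1.67 ± 0.21 and Cidea, whose fitted value depends on pools near 0, at -4.00 ± 0.40.

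Camera with the preset correlation called the interaction of 20 lists, and with an estimated correlation none (lowest adjusted p = 0.543, camera in limma). Median interactions were negative for extracellular matrix (-0.65), stellate cells (-0.35), recruited macrophages (-0.50), endothelium (-0.32), pericentral genes (-0.63) and fatty acid oxidation (-0.23). They were also negative for lipid droplets (-0.60), NRF2 targets (-0.22), cell cycle (-0.30), p53 targets (-0.30), beta-catenin targets (-0.73), chemokines (-0.33), interferon-stimulated genes (-0.63), class II antigen presentation (-0.51) and clock genes (-0.52). They were positive for B and plasma cells (0.47), hepatocyte identity (0.15), cholesterol synthesis (0.37), acute phase proteins (0.36) and male-biased genes (0.65).

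In all 13 called genes the interaction opposed the larger of the separate changes. The interaction subtracts both separate changes and shares their pools, so an opposite sign is favoured even without an effect. The share among other genes was not computed, so the 13 of 13 is no evidence of a weaker joint effect. With a pseudocount of 0.1, 9 of the 13 stayed past the threshold. Compression of low values by the pseudocount is argued against for 4 of them, Apoa4, Gstm3, Sulf2 and Sqle, which read at least 6.86 in every liver pool. Cidea, Enho, Pitx3 and Srgap3, each with some pools at low values, did not stay, so compression stays open there. Moxd1, Dbp and Cyp2a22 are among those 9 but do not bear on this. Dbp and Cyp2a22 were lowest in the normal-diet oil pools, and a smaller pseudocount only enlarges their rises and the fall of Moxd1 to 0. Normal-diet oil livers that were out of place cannot be told apart from an interaction, since the interaction cannot be estimated without them and a shift of these livers alone would give one. In Apoa4, Cidea, Enho, Scara5 and Sqle the highest and lowest of the 3 exposed combinations differed by at least 1.225 (log2). These genes were picked for a range above 1, so it does not test whether each exposure alone carried the change, a biological explanation. The changes with CCl4 alone, diet alone and both were 5.32, 1.86 and 4.73 for Apoa4 and -4.12, -0.27 and -2.72 for Sqle. There the diet alone fell short of the joint change, which argues against that explanation. For Enho they were -3.38, -2.37 and -3.60. For Scara5 they were -0.46, -1.82 and 0.27. The diet alone lowered Scara5 (limma adjusted p = 0.00161) while both exposures did not (limma adjusted p = 0.241), which also argues against that explanation. Cidea, near 0 in some pools, had 4.57, -0.06 and 0.51. Neither the diet alone nor both exposures passed for Cidea (limma adjusted p = 0.930 and 0.207), so it had no called joint change to carry. In the other 8 genes the combinations lay within 1, which decides nothing on the oil livers. Outside Apoa4, Sqle, Scara5 and Cidea the biological explanation stays open and was not tested.

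Clock genes set the normal-diet oil livers apart from the other 6 pools. Scaling between libraries is argued against, since Dbp rose by at least 4.186 (log2) in the joint comparison under 3 other scalings. Collection at another hour or feeding state stays open. The shift between livers correlated with tumour 2 minus tumour 1, a pair on the same diet and treatment. Pearson r was 0.8115 (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2e-05). Spearman rho was 0.718 (permutation p = 0.00017, adjusted p = 0.00017). Both cover 22 genes, which are not independent replicates, and r was 0.696 without Dbp and Per3. Any cause that moves clock genes together would give such a correlation, and the tumours differed in other genes as well. The correlation and its p-values therefore do not favour the hour over another cause. Shifts by diet and by CCl4 could instead add up on the log2 scale. The joint change minus their sum, in its direction, had a median of -0.9354 and was negative in 21 of 22 genes. The 95% interval over genes, which are not independent, was -1.232 to -0.4569, and medians were -1.134 at 12 and -0.6298 at 24 weeks. That argues against additive shifts as the whole cause only if the normal-diet oil livers were in place. A shift of these livers alone enters both terms and would give a negative value too. Additive shifts beside such a shift therefore stay open. The labels give no hour of collection, and an effect of diet and CCl4 on the clock that does not add up stays open and was not tested.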

How the results depend on the processing

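The edgeR and DESeq2 fits in this part were chosen after seeing the data, and the other alternatives were planned. Counts are genes past the threshold, in the order CCl4 on normal diet, diet alone, joint exposure, CCl4 on Western diet, interaction, duration and tumours, with 3285, 252, 3278, 862, 13, 0 and 123 as reported. The pseudocount of 0.1, the stricter filter, median-ratio factors and edgeR stayed within 1.5 times these counts, except that edgeR called 1 gene for duration. Without a filter, with more genes tested, the counts were 1353, 0 (limma, with 2442 at an unadjusted p under 0.05), 1887 and 3 in the first 4 comparisons and 0 (limma, with 1346) for the interaction. With all 10 libraries in 1 fit they were 437, 4, 796, 6 and 0 (limma, with 320 unadjusted). Quantile normalization gave 134 for diet alone, 470 for CCl4 on Western diet and 214 for tumours. Without the trend, diet alone gave 125 and the interaction 7. Without the duration term, diet alone gave 121, CCl4 on Western diet 203 and tumours 388, and array weights gave 3 for tumours. DESeq2 gave 570 for diet alone, 1319 for CCl4 on Western diet, 132 for the interaction, 90 for duration and 745 for tumours. Leaving out 1 library gave ranges of 1021 to 3659, 17 to 390, 1214 to 3136, 29 to 891, 0 to 79, 0 to 1 and 0 to 2394. Lists called by camera numbered 25, 16, 26, 26, 20, 20 and 21, and 0 in every comparison with an estimated correlation. Fry called 22, 0, 19, 8, 0, 0 and 0. No called gene changed direction under any of these settings, and of 8427 alternative values for 464 results on single genes 6716 kept direction and side of the threshold, 1676 fell short of it (856 of them with a library left out), 24 newly passed and 11 turned. Those 11 were not called to begin with. In the joint comparison, Cyp2e1 turned with quantile normalization (0.21), and Cyp7a1 ran from -0.71 without the normal-diet oil pool of 12 weeks to 1.01. In tumours, Timp1 turned without the duration term (0.14). With a library left out, the genes that turned ran from -0.56 to 0.58 for Timp1 (0.25 without tumour 2), -0.43 to 3.08 for Afp, -1.39 to 5.68 for Gpc3, -2.30 to 0.76 for Glul, -0.55 to 0.16 for Scd1 (0.05 without tumour 2) and -0.90 to 0.49 for Cd36. The opposite sign came without tumour 2 for Afp, Gpc3, Glul and Cd36, and without the Western-diet CCl4 pool of 24 weeks or tumour 2 for Timp1 and Scd1. Apart from the smaller number of libraries where 1 was left out, the cause was not tested. The larger number of genes tested without a filter, 17615 against 12648, cannot by itself explain the 0 calls for diet alone. The smallest adjusted p there was 0.000195 in the main limma fit. Depth limits low values: 3 reads correspond to a value of 0.0862 to 0.137 in these libraries.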

Other observations

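All tests of explanations in this part were chosen only after the results had been seen. Stress and damage genes moved with the joint exposure compared with normal diet and oil. Of p53 targets, 12 of 20 measured members rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 2.84e-05, adjusted p = 0.339 with an estimated correlation). The receptor gene Eda2r rose by 3.17 ± 0.25 and the cell cycle inhibitor Cdkn1a by 1.51 ± 0.31. Of NRF2 targets, 9 of 24 measured members rose and 6 fell, or 10 and 8 adjusted over the list alone (camera adjusted p = 0.435, adjusted p = 0.620 with an estimated correlation), with carbonyl reductase Cbr3 at 2.38 ± 0.21 and Gstp1 at -2.13 ± 0.22. Of endoplasmic reticulum stress genes, 3 of 22 measured members rose and 10 fell, or 4 and 11 adjusted over the list alone (camera adjusted p = 0.00659, adjusted p = 0.385 with an estimated correlation), with the stress factor Atf3 at 2.30 ± 0.26 and asparagine synthetase (Asns) at -1.71 ± 0.30. Acute phase genes split, and 5 of 24 measured members rose and 9 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.0806, adjusted p = 0.562 with an estimated correlation), with metallothionein Mt2 at 2.55 ± 0.33 and serum amyloid P (Apcs) at -1.07 ± 0.16. Of female-biased genes, 11 of 17 measured members rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00330, adjusted p = 0.321 with an estimated correlation), with Cyp2a4 at 5.13 ± 0.59, a member of a close paralog family. In tumours the median of that list was 0.07 while camera called it lower (camera adjusted p = 0.0489, adjusted p = 0.565 with an estimated correlation).

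Endothelial and oxidation genes rose in part in the joint comparison. For endothelial markers, 10 of 22 measured members rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 0.000157, adjusted p = 0.385 with an estimated correlation), with the progenitor antigen Cd34 at 1.76 ± 0.27. Of T and NK cell markers, 4 of 14 measured members rose and 2 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.0360, adjusted p = 0.339 with an estimated correlation), with the chemokine Ccl5 at 1.65 ± 0.23. Of B and plasma cell markers, 2 of 8 measured members rose and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.867, adjusted p = 0.949 with an estimated correlation). For fatty acid oxidation, 8 of 28 measured members rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00283, adjusted p = 0.321 with an estimated correlation), with the carnitine transferase Cpt1a at 1.11 ± 0.14. For fatty acid and triglyceride synthesis, 8 of 22 measured members rose and 3 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0937, adjusted p = 0.418 with an estimated correlation). For glucose metabolism, 9 of 25 measured members rose and 4 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0420, adjusted p = 0.385 with an estimated correlation), with the pyruvate kinase Pkm at 1.58 ± 0.17. The neutrophil list had 4 tested members, the red blood cell list 2, and the pancreas and the fat and muscle lists 1 each, too few for a test. Their highest values were 1429 for Lcn2, 215 for Alas2, 29.1 for Cela1 and 45.6 for Cfd. Hba-a2 and Hbb-b1, globin genes, are listed at 0 in all 10 libraries.

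The tumours differed from each other by a median of 0.420 (log2, absolute, over tested genes), against 0.143 to 0.205 between the pools of 12 and 24 weeks of a combination. Albumin reads, 17.682% of tumour 2 (Wilson 95% interval 17.668 to 17.695) and 7.288% of tumour 1 (7.277 to 7.298), are argued against as the cause, since the smallest ratio of tumour to pool difference was 2.079 (95% interval 2.016 to 2.142) after quantile normalization. Single animals against pools of 4 cannot be told apart from a difference between tumours, since pooling 4 mice can lower a spread up to 2-fold and the smallest ratio was 2.051 (95% interval 1.998 to 2.118). Both intervals resample genes, which are not independent. A biological difference between the tumours stays open and was not tested.

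For duration, the pools allow 35 splits into groups of 4, of which 32 could be fitted, and 32 of the 32 called as many genes as the real split. Since the real split called 0 genes in limma, with 1475 at an unadjusted p under 0.05, 1 by edgeR and 90 by DESeq2, that outcome was fixed and says nothing about chance. The highest count among the other splits was 358, from 1 contrast that 2 of the splits share: the CCl4 pools of 24 weeks against those of 12 weeks, with each oil combination whole on a side. That count was picked as the highest of 32, so it does not by itself show a structure of the samples. Whether it reflects duration, a batch or chance was not tested.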
